A study of Mus musculus with 4 samples.

How the data were processed

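RNA from 2 GIC and 2 non-GIC samples was compared, each on its own array. Per the labels, 5 µg of total RNA was labelled with biotin by in vitro transcription with the Affymetrix One-Cycle procedure. The deposited table holds 1 value per probe set and array on a log2 scale, for 45101 probe sets. The log base was read from the values, which range from 2.75 to 15.12. The arrays had near-equal quantiles, so the deposited values had already been brought to a common distribution. The background correction, summarisation and normalization are not given in the sources used here. Detection calls were not used here, so no gene is called absent. No array pair held identical values (0 of the pairs). The labels do not say that the arrays of a subline came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

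Probe sets were named through the platform's annotation table, with symbols updated through the Entrez identifier to the gene table of assembly GRCm38.p6, which was used only for names and for the order of neighbouring genes. Of 45101 probe sets, 34945 had 1 gene symbol, 932 had several and 9211 were unnamed here. For 34741 the symbol came from the identifier. Probe sets with several genes or none and 64 control probe sets were left out of the gene tests. Each gene was represented by the probe set with the highest mean over the 4 arrays. A gene was tested if at least 2 arrays lay above the 40th percentile of all values (5.97).

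Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, group as the only term), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit had 2 residual degrees of freedom per gene and 2.72 prior degrees of freedom. Fold changes are GIC minus non-GIC. With 2 arrays per group an exact permutation test of a single gene cannot go below p = 0.33. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 25 lists with enough tested genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

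The groups, tests, 27 gene lists, alternatives and the rule for named genes were fixed before the data were examined. Of 523 listed genes, 495 had a probe set here, and the rest were not analysed here. The rule named Sox11 and the p53 and HRas genes as checks, the 10 largest increases and decreases among changed genes whose groups did not overlap, up to 4 changed members of each list or else the 2 with the smallest p, and the sex-linked genes. It gave 71 genes; Oasl2 was named outside it, after its value was seen, to complete the members that passed in its list. For the p53 and HRas checks no named probe set was used here.

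The procedure was tested on simulated data for GIC against non-GIC, with 200 of 13366 genes changed in each of 20 simulations. It recovered 11.1% of changes of 1 on the log2 scale, 79.9% of changes of 2, 92.1% of changes of 3 and 96.9% of changes of 4. Of its calls 4.3% were false. The simulated noise was independent between genes and drawn from the fitted spread. Shifts shared by many genes on an array were not simulated, so this share does not carry over to the real calls.

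The alternatives were the replicate number as a block, quantile normalization, median centring, no level filter or one at the 60th percentile, the mean of a gene's probe sets, leaving out probe sets that can bind several transcripts, eBayes without a trend or robust, camera with an estimated correlation, fry, and leaving out each array in turn. With 1 array left in a group, that array is assumed to vary like the other group. Camera with an estimated correlation rests on the 2 residual degrees of freedom, or fewer with an array left out. It has little power here, so a call lost with it is weak evidence against a list. The estimates ranged from -0.08 for the astrocyte list to 0.96 for cholesterol synthesis, with 0.86 for cell cycle and 0.56 for interferon. Where members of a list move together more than the preset correlation allows, camera at the preset value gives p-values that are too small. A call made only at the preset value is therefore weak evidence for a list too. A block with crossed replicate numbers was added after seeing the data. Neighbouring genes were scanned with the median log2 fold change in windows of 50 genes along each chromosome, against the largest window medians after 1000 shuffles of gene order, and the run with the highest window was compared with 10000 random lists of genes outside it, matched on mean signal.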

Results

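Gene expression was measured on 4 oligonucleotide arrays, 2 for each of a pair of sublines derived from mouse neural stem cells. The stem cells came from the embryonic telencephalon of p53-null C57BL/6 mice, were transfected with a vector for GFP and an activated HRas, and were sorted for GFP. Per the labels, one subline was tumorigenic and is called glioma-initiating cell-like (GIC), and the other was nontumorigenic (non-GIC). The single comparison in the design asks which transcripts differ between a tumorigenic and a nontumorigenic subline that carry the same oncogene. Any other difference between these sublines goes along with tumorigenicity, so no gene difference can be assigned to tumorigenicity itself. The deposited value of each probe set is a log2-scale signal, with array medians of 6.58 to 6.63. Of 18193 genes with a probe set, 13366 passed the level filter and were tested. The number of arrays limits the precision of every value below.

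Arrays of the same subline resembled each other more than arrays of different sublines. Over the tested genes, Pearson's r was 0.978 between the non-GIC arrays and 0.976 between the GIC arrays, and 0.918 to 0.954 across sublines. Genes are not independent replicates, and this comparison carried no test. At least 2-fold differences were found for 403 genes between the non-GIC arrays and for 423 genes between the GIC arrays. Across sublines the number ranged from 847 to 1634 genes. The 3' minus 5' signal of the actin control probe sets lay between 0.09 and 0.12 (log2) on all 4 arrays. That of the Gapdh control was -0.18 and -0.22 on the non-GIC arrays and -0.31 and -0.29 on the GIC arrays. The pyruvate carboxylase control had 0.42 and 0.47 on the non-GIC arrays, 0.72 on GIC replicate 1 and 0.51 on GIC replicate 2, and the transferrin receptor control lay between 0.84 and 0.97. Xist, the noncoding RNA of the inactive X chromosome, had a mean signal of 11.54 ± 0.06 in GIC and 11.07 ± 0.04 in non-GIC (SD, n = 2), and the Y-linked Eif2s3y, Kdm5d and Uty lay below the filter level of 5.97 on every array.

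Sox11, which encodes a transcription factor of immature neurons, was among the genes with the largest decrease in GIC. Its mean signal was 5.27 ± 0.12 in GIC and 10.70 ± 0.02 in non-GIC (SD, n = 2). This is a log2 fold change of -5.43 (SE 0.14, limma adjusted p = 0.00433), or 43.0-fold lower. All 6 Sox11 probe sets were lower in GIC, with log2 fold changes from -2.39 to -5.82. Sox11 is named because the study behind these arrays is known to concern it. The p53 and HRas transcripts themselves were not analysed here.

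**Figure D1:**
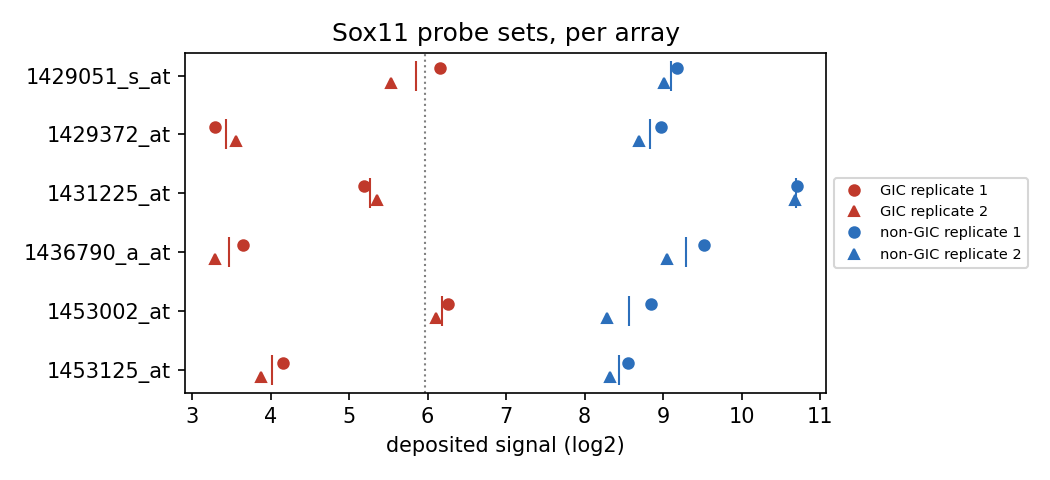
Signal of the Sox11 probe sets (log2, horizontal axis) on each of the 4 arrays; circles and triangles are replicates 1 and 2, short vertical bars the group means, and the dotted line the filter level of 5.97. The non-GIC arrays lie above the GIC arrays for all 6 probe sets.

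GIC and non-GIC differed in 257 genes, of which 165 were higher and 92 lower in GIC. Among the genes higher in GIC were Klhl13, an adaptor of a cullin ubiquitin ligase (63.6-fold), the interferon-induced membrane protein Ifitm1 (58.4-fold) and the secreted matrix protein Smoc2 (42.2-fold). Among those lower in GIC were the small heat shock protein Hspb8 (54.2-fold), the lysosomal protease cathepsin C, Ctsc (38.8-fold), and Vat1l (32.2-fold). The test was limma's moderated test with Benjamini-Hochberg adjustment. A change of at least 2-fold was found in 158 of the higher and 89 of the lower genes. At an unadjusted p under 0.05 there were 2386 genes. The groups did not overlap in 50.4% of tested genes. Chance gives 33.3% on average over the 3 splits of the arrays into 2 and 2. Genes on an array move together, so 1 set of arrays can lie well above that average by chance. The count of changed genes was 77 without GIC replicate 1, 188 without GIC replicate 2, 12 without non-GIC replicate 1 and 56 without non-GIC replicate 2. The Smoc2 fold change ranged from 27.3-fold without non-GIC replicate 2 to 65.3-fold without non-GIC replicate 1.

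The 10 largest increases also included Wfdc2, a secreted whey acidic protein-type protein (log2 fold change 5.34, SE 0.22, adjusted p = 0.00722), and the Runt-family transcription factor Runx3 (4.72, SE 0.20, adjusted p = 0.00722). The kinase Rps6ka6 rose by 5.00, the guidance factor Sema3d by 4.90, the G-protein regulator Rgs2 by 4.85, the matricellular protein Ccn5 by 4.60 and the kinase Ripk4 by 4.54 on the log2 scale, with adjusted p from 0.0144 for Rps6ka6 to 0.0368 for Ripk4. Omitting GIC replicate 1 or GIC replicate 2 moved the increase of Sema3d to 16.9-fold or 52.8-fold, that of Rgs2 to 17.4-fold or 48.0-fold and that of Ripk4 to 37.0-fold or 14.5-fold. Omitting non-GIC replicate 1 or 2 moved that of Ccn5 to 15.3-fold or 38.2-fold. Wfdc2 and Ccn5 lie on chromosome 2 (assembly GRCm38.p6) in a window of 50 neighbouring tested genes whose median log2 fold change was 1.14. Among the 10 largest decreases, the caveolar coat protein Cavin2 fell by 4.81 and Tmem35a, a chaperone of nicotinic receptors, fell by 4.68. The actin-associated protein Pdlim1 fell by 4.32, the growth factor binding protein Igfbp7 fell by 4.16 and the smooth muscle calponin Cnn1 fell by 4.03. The decrease of Cavin2 was 17.1-fold without GIC replicate 1 and 46.0-fold without GIC replicate 2, and that of Cnn1 was 10.2-fold without non-GIC replicate 1 and 26.3-fold without non-GIC replicate 2. The glucose transporter Slc2a3 was 9.75 ± 0.10 in non-GIC and 5.87 ± 0.04 in GIC (SD, n = 2; adjusted p = 0.00542). In 91 changed genes 1 group had its mean under the filter level. There the fold change can be understated, and so can the spread between arrays, which would make p too small. The 91 genes include Klhl13, Sox11, Hspb8 and Vat1l, so the order of the largest changes is uncertain too. In 7 changed genes another probe set past the filter went the other way.

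**Figure D2:**
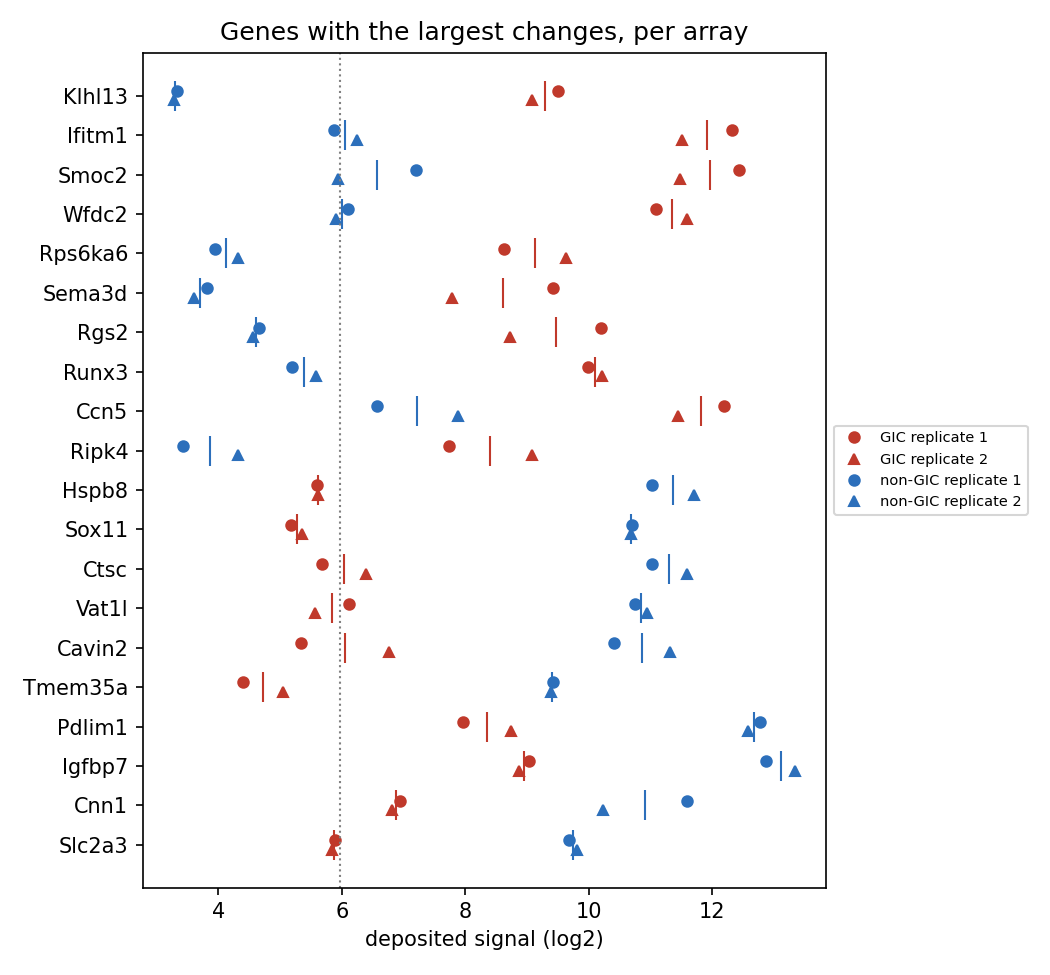
Signal (log2, horizontal axis) of the 10 genes with the largest increase and the 10 with the largest decrease in GIC, on each of the 4 arrays; circles and triangles are replicates 1 and 2, short vertical bars the group means, and the dotted line the filter level of 5.97. Klhl13 has 9.08 and 9.50 in GIC against 3.28 and 3.32 in non-GIC.

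Gene groups of the neural lineage changed in single members. Of 21 tested genes of the neural stem and progenitor list, the intermediate filament Nes fell by 2.07 on the log2 scale (adjusted p = 0.0459) and the radial glial lipid-binding protein Fabp7 was 2.84-fold lower (adjusted p = 0.0258). The surface glycoprotein Cd24a rose by 1.22 on the log2 scale (adjusted p = 0.0356), and 18 did not pass. Both GIC arrays lay under the filter level for Fabp7, at the same value of 5.23. Of 19 neuronal differentiation genes, Sox11 and the dendritic protein Map2 (log2 fold change -2.29, adjusted p = 0.019) fell, the neuroendocrine factor Insm1 rose (2.69, adjusted p = 0.0122), and 16 did not pass. Both lists had 1 gene higher and 2 lower when adjusted over the list alone. Neither list as a whole passed camera, a test of a list against all other genes (adjusted p = 0.508 for both). No gene of the astrocyte list (12 tested) or the oligodendrocyte lineage list (11 tested) passed over all genes. Adjusted over the list alone, 2 astrocyte genes were higher and 1 lower, and 1 oligodendrocyte lineage gene was higher. Clu had a log2 fold change of 2.39 (adjusted p = 0.0772), Fgfr3 one of 0.87 with 1 other probe set going the other way, Pdgfra one of 2.26 (adjusted p = 0.0504) and Ugt8a one of 0.18. The Pdgfra value passed the threshold with quantile normalization, with the filter at the 60th percentile and with the mean of its probe sets. It did not pass with median centring, without a filter, with the replicate block, or with eBayes without a trend or robust.

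**Figure D3:**
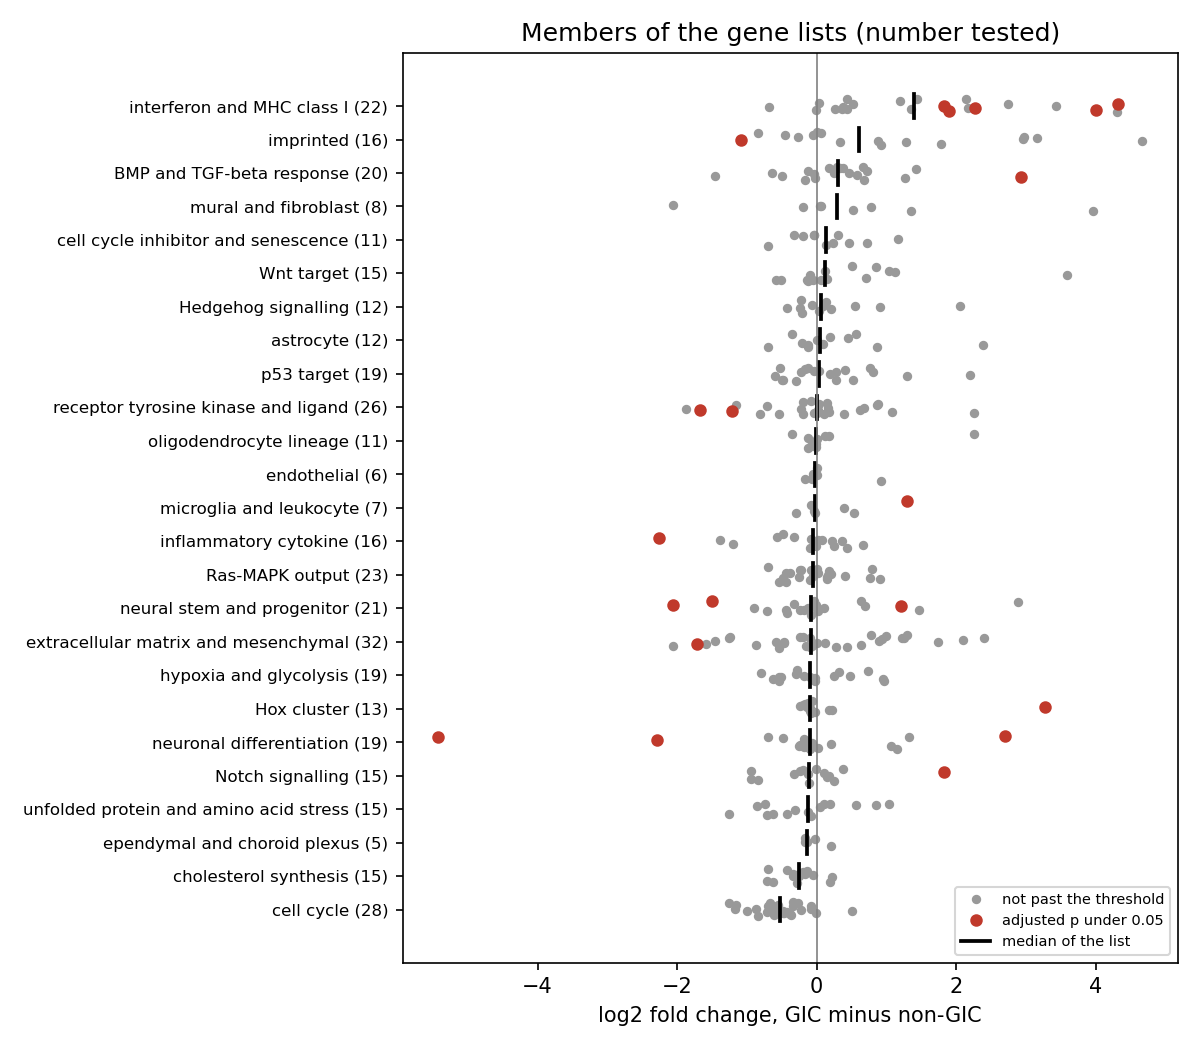
Log2 fold change (GIC minus non-GIC, horizontal axis) of each tested member of the 25 tested gene lists; red points passed an adjusted p of 0.05 over all genes, grey points did not, black bars are list medians, and the number of tested genes is in brackets. The interferon and MHC class I list has the highest median (1.39) and the cell cycle list the lowest (-0.52).

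The interferon response and MHC class I list had a median log2 fold change of 1.39 over 22 tested genes, of which 5 passed. Camera with a preset correlation gave an adjusted p of 3.47e-08. The call was lost with an estimated correlation (adjusted p = 0.947) and with fry (adjusted p = 0.326). The estimate was 0.56, well above the preset value, so the first of these p-values may be far too small. The ISG15 protease Usp18 rose 19.9-fold (adjusted p = 0.0428) and the oligoadenylate synthetase-like Oasl2 rose 16.0-fold (adjusted p = 0.0484). Both leaned on GIC replicate 1, with 11.4-fold for Usp18 and 9.29-fold for Oasl2 without it, and 34.8-fold and 27.5-fold without GIC replicate 2. The signal transducer Stat2 rose 4.83-fold (adjusted p = 0.0343), the class I heavy chains H2-D1 and H2-K1 rose 3.73-fold and 3.53-fold (adjusted p = 0.0255 and 0.0288), and 17 genes did not pass. The H2-D1 and H2-K1 probe sets are of a kind that can bind several related transcripts, and 1 of the other H2-D1 probe sets went the other way. There were 12 genes higher and 1 lower, adjusted over the list alone. The mean deviation of the list from each gene's average was 1.21 on GIC replicate 1 and 0.38 on GIC replicate 2, against -0.80 and -0.79 on the non-GIC arrays. The number of members past the threshold was 2 without GIC replicate 1, 10 without GIC replicate 2, and 0 without either non-GIC array.

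The cell cycle list had a median log2 fold change of -0.52, with none of its 28 tested genes past the threshold over all genes or adjusted over the list alone. Camera with a preset correlation gave an adjusted p of 0.000118. The call was lost with an estimated correlation (adjusted p = 0.947) and with fry (adjusted p = 0.619). Here the estimate was 0.86, so the p-value at the preset correlation may again be far too small. The replication licensing factor Mcm2 had a value of -1.25 (adjusted p = 0.182) and the transcription factor Foxm1 one of -1.17 (adjusted p = 0.126). The mean deviation was -0.62 on GIC replicate 1, 0.10 on GIC replicate 2, and 0.27 and 0.26 on the non-GIC arrays. Without GIC replicate 1 the median was -0.19 and the adjusted p 0.146.

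No gene of the Ras-MAPK output list (23 tested), the p53 target list (19), the cell cycle inhibitor and senescence list (11), the hypoxia and glycolysis list (19), the unfolded protein and amino acid stress list (15) or the cholesterol synthesis list (15) passed, over all genes or over the list alone. The values of the members with the smallest p were 0.91 for the ERK phosphatase Dusp6 and 0.80 for Spry1, 1.30 for Btg2 and -0.60 for Phlda3, -0.70 for the lamin Lmnb1 and 0.72 for Rbl1. They were 0.95 for Adm and 0.96 for Pdk1, -1.26 for asparagine synthetase, Asns, and 1.04 for Atf3, and -0.71 for Nsdhl and -0.70 for Mvd. Camera's adjusted p for these lists lay between 0.598 for cholesterol synthesis and 0.870. Cholesterol synthesis genes differed between the non-GIC arrays, with a mean deviation of 0.99 on replicate 1 and -0.72 on replicate 2. Without non-GIC replicate 1 the list was higher in GIC (adjusted p = 0.00056), and without non-GIC replicate 2 it was lower (adjusted p = 8.27e-08). Both calls were lost with an estimated correlation (adjusted p = 0.965 and 0.959) and with fry (0.562 and 0.460).

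Signalling lists changed in few members. The Notch ligand Dll1 rose by 1.82 (adjusted p = 0.0439; 15 genes of the Notch list tested), the growth factor Bmp2 by 2.92 (adjusted p = 0.0137; 20 of the BMP and TGF-beta list tested) and the homeobox gene Hoxd8 by 3.28 (adjusted p = 0.00789; 13 of the Hox list tested) on the log2 scale. Of 26 tested receptor tyrosine kinases and ligands, the receptor Met fell by 1.67 (adjusted p = 0.0437) and Fgf2 fell by 1.22 (adjusted p = 0.0307). The NF-kappaB inhibitor Tnfaip3 fell by 2.26 (adjusted p = 0.0345; 16 of the inflammatory cytokine list tested). No other member of these lists passed over all genes. Adjusted over the list alone, 1 gene was higher and 2 lower in the Notch list, 1 higher in each of the BMP and Hox lists, 3 higher and 2 lower among the receptor kinases, and 3 lower among the cytokines. No gene of the Hedgehog list (12 tested) or the Wnt target list (15 tested) passed over all genes, and 2 in each were higher over the list alone. Gli2 had a value of 2.05 (adjusted p = 0.0766), Ptch1 0.90, Dkk2 3.59 (adjusted p = 0.0854; 6.48-fold without non-GIC replicate 1 and 22.3-fold without non-GIC replicate 2) and Tcf7l2 0.85. Camera's adjusted p for these lists was 0.386 or more. Without non-GIC replicate 2 it was 0.0173 for the BMP and TGF-beta list, in the upward direction, a call lost with an estimated correlation (0.959) and with fry (0.224).

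Of 32 tested extracellular matrix and mesenchymal genes, the smooth muscle actin Acta2 fell by 1.71 on the log2 scale (adjusted p = 0.0348) and 31 did not pass. Adjusted over the list alone, 1 was higher and 5 were lower. The list's mean deviation was 0.45 on GIC replicate 1 and -0.38 on GIC replicate 2, and -0.23 and 0.17 on the non-GIC arrays. Camera gave an adjusted p of 0.870 with all arrays and, without GIC replicate 1, of 0.00323 in the downward direction. That call was lost with an estimated correlation (adjusted p = 0.982) and with fry (0.595). Of 16 tested imprinted genes, Peg10 fell by 1.09 (adjusted p = 0.0335) and 15 did not pass. Adjusted over the list alone, 6 were higher and 1 was lower, and camera gave an adjusted p of 0.144. It was 0.0109 without GIC replicate 1 and 0.0172 without non-GIC replicate 1, in the upward direction. These calls were lost with an estimated correlation (adjusted p = 0.982 and 0.965) and with fry (0.233 and 0.562).

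No list of markers of other cell types passed camera (adjusted p = 0.590 or more). Of 7 tested microglia and leukocyte genes, the lipopolysaccharide co-receptor Cd14 rose by 1.30 on the log2 scale (adjusted p = 0.037), over all genes and over the list alone. No endothelial (6 tested), mural and fibroblast (8) or ependymal and choroid plexus gene (5) passed over all genes, and 1 mural and fibroblast gene was higher over the list alone. Igfbp4 had a value of 3.96 (adjusted p = 0.0584; 3.16 without non-GIC replicate 1 and 4.77 without non-GIC replicate 2), Col1a1 -2.06 (GIC replicates at 13.59 and 10.70, non-GIC at 13.84 and 14.57), Flt1 0.92, Cldn5 -0.16, Tmem212 0.21 and Rsph1 -0.17. The mural and fibroblast list had a mean deviation of 0.92 on GIC replicate 1 and -0.36 on GIC replicate 2. Of the erythroid list 1 gene was tested, Hbb-bh1 (-0.06, adjusted p = 0.824), and of the sex-linked list Xist alone (0.47, adjusted p = 0.219), so these lists had no group test. The median had a sign other than the mean or the camera direction in the oligodendrocyte, extracellular matrix, receptor kinase, Hox, leukocyte and endothelial lists.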

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

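The count over other splits was chosen after the result was seen. Probe sets with several genes or none lie outside the gene comparison and were tested in the same way. Of 3475 such probe sets past the filter, limma called 21 higher and 10 lower in GIC. The largest increase among them was 6.16 on the log2 scale, above the 5.99 of Klhl13. That probe set had 12.21 and 10.01 on the GIC arrays and 4.97 and 4.93 on the non-GIC arrays. The others are given as counts, and no explanation was tested.

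The 4 arrays can be split into 2 and 2 in 3 ways. Of these splits, 1 called as many genes as the real one, which is the real split itself, with 257 genes. The highest count among the other splits was 0 genes with limma, and they had 67 and 418 genes at an unadjusted p under 0.05. With 3 splits no share under 0.05 can be reached.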

How the results depend on the processing

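The crossed block was chosen after seeing the data. Over scaling, filter, probe set and eBayes choices, 198 to 261 genes changed and both called lists kept their camera call; of 233 changed genes still tested without probe sets that can bind several transcripts, 1 turned sign, Sdc4 (1.86 to -0.12), named after its value was seen. For array similarity, the lowest r within a subline exceeded the highest across sublines by 0.0106 to 0.0392. With the replicate block 29 genes changed (21 higher, 8 lower), the imprinted list passed (adjusted p = 0.0404), no other list call changed, and 25 of 38 called named genes lost their call, against 11 to 34 with 1 array left out. The labels do not say whether equal numbers pair samples, and the correlation of same-numbered deviations (-0.324) cannot settle it. With crossed numbers 685 changed (457 higher, 228 lower). Leaving out 1 array gave 12 to 188 genes (5 to 142 higher, 7 to 46 lower) and 2 to 4 lists, with fewer samples in the fit. With all arrays none of the 25 lists passed with an estimated correlation (0 lists; interferon and cell cycle 0.947) or fry (0 lists; 0.326 and 0.619). Without GIC replicate 2 fry passed interferon (0.0277), cell cycle (0.0300) and imprinted (0.0379). The cause was not tested.

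Leave-one-out adjusted p by camera at the preset correlation ranged from 2.5e-12 to 0.146 for cell cycle, 0.00323 to 0.634 for extracellular matrix, 0.0109 to 0.247 for imprinted, 8.27e-08 to 0.844 for cholesterol synthesis and 0.0173 to 0.597 for BMP. Lists not called with all arrays turned direction in some of these fits, with ranges of 0.247 to 0.947 (Ras-MAPK), 0.580 to 0.955 (hypoxia), 0.355 to 0.916 (Hox), 0.844 to 0.987 (endothelial), 0.102 to 0.597 (mural), 0.844 to 0.935 (receptor kinase), 0.629 to 0.958 (ependymal), 0.293 to 0.955 (senescence) and 0.336 to 0.895 (unfolded protein); the matrix and cholesterol lists turned too. Uncalled lists also turned with quantile normalization (oligodendrocyte and endothelial, 0.972), median centring (receptor kinase, 1), no filter (oligodendrocyte 0.965; Notch and endothelial 0.986), the 60th percentile (receptor kinase and Hox, 0.641), the probe set mean (Hox, 0.744), fewer probe sets (hypoxia 0.861, receptor kinase 0.896, Hox 0.954) and fry (Hox, 0.569). The causes were not tested. Nsdhl and Mvd, not called, ranged over -1.528 to 0.106 and -1.621 to 0.223 with 1 array left out. Offsets before log2 were not run, since the values are log2. Signal near background limits low genes.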

Other observations

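The neighbour scan, its test of signal level, the lists of contractile and fibroblast matrix genes and the tests of the interferon and cell cycle lists were chosen after seeing the data. So were the genes named here outside the rule. Bounds for gene families and copy number were set before their test values were seen.

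Of 25 tested genes of the contractile and actin cytoskeleton, the calponin Cnn1, the myosin light chain Myl9, Acta2, the tropomyosins Tpm1 and Tpm2 and the leiomodin Lmod1 fell, the matricellular Ccn2 rose, and 18 did not pass. Myl9 fell by 2.35, Tpm2 by 1.63 and Tpm1 by 0.75 on the log2 scale. Over that list alone 11 were lower and 2 higher. The number lower was 2 without GIC replicate 1, 3 without GIC replicate 2, 0 without non-GIC replicate 1 and 1 without non-GIC replicate 2, over all genes. Camera gave an adjusted p of 8.63e-05 over the 2 lists added here, fry one of 0.0456 and camera with an estimated correlation one of 0.173. Acta2, Cnn1, Myl9 and Tagln had been seen before the list was written, so its direction is not independent evidence. Of 17 tested fibroblast matrix genes, Smoc2 (5.40) and dermatopontin, Dpt (4.11), were higher and 15 did not pass. Over that list alone 4 were higher and 1 was lower. Camera gave an adjusted p of 0.0115, camera with an estimated correlation one of 0.442 and fry one of 0.397; Smoc2, Dpt and Aspn had been seen before. Dpt rose 10.4-fold without GIC replicate 1 and 28.7-fold without GIC replicate 2. This list leaned on single arrays, with a mean deviation of 1.23 on GIC replicate 1, 0.07 on GIC replicate 2, -1.08 on non-GIC replicate 1 and -0.21 on non-GIC replicate 2. The camera call was lost without GIC replicate 1 (adjusted p = 0.0991) and without non-GIC replicate 1 (adjusted p = 0.161).

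Imprinted genes held large values that missed the threshold over all genes. Dlk1 had a log2 fold change of 3.17 (SE 0.44, adjusted p = 0.0509; 2.53 without GIC replicate 1 and 3.80 without GIC replicate 2), Mest of 2.98 (SE 0.49, adjusted p = 0.0733) and Peg3 of 1.79 (SE 0.31, adjusted p = 0.0829), each higher on both GIC arrays than on both non-GIC arrays.

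Log2 fold changes of neighbouring genes leaned the same way along chromosomes, though most genes in the runs below were not called. With gene order and chromosome from assembly GRCm38.p6, 27 runs of neighbouring genes passed the scan, 14 higher and 13 lower in GIC. On chromosome 5 76.6% of 853 genes were higher (median 0.26), and on chromosome 15 24.4% of 541 genes were (median -0.18). The run with the highest window lay on chromosome 2 from Snrpb2 to Rtf2, with 280 genes, a median of 0.49 and 27 of the 165 genes called higher. It also held 2 genes called lower. Runs were picked for a shift of their values, so the median and these counts are not independent of the choice. Its highest window, from Oser1 to Slc35c2, had a median of 1.14 over 50 genes, and the median deviation was 0.51 on both GIC arrays and -0.61 and -0.53 on the non-GIC arrays.

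The tables argue against level-dependent normalization as the cause of this run. Of 10000 random lists of genes outside it, matched on mean signal, nearly all had a median under 0.02, with a middle value of -0.021. The run's own median was 0.49, but the run was picked for its shift. Genes that share a symbol stem do not carry it alone, because the 203 genes with a stem of their own had a median of 0.638. Related genes with unlike symbols were not told apart, and this median too was taken within the picked run. A difference in gene copy number between the sublines is a candidate explanation that these arrays cannot decide. From 70% to 81.8% of the run's genes were higher in GIC over the 4 array pairs. The bounds for and against a copy number difference were set on the lowest pair, whose 70% lay between them. This share was taken on a run picked for its shift and counts genes that hardly differed, so it cannot decide the question. A regional difference in regulation was not tested.

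The higher interferon list may reflect leukocytes, a single array, RNA quality or the cells themselves. The 16 leukocyte markers with a probe set had a median log2 fold change of 0.079, and the 7 that passed the level filter one of -0.02. Abundant leukocyte transcripts rose less than the list, with 0.39 for Lyz2, 0.08 for Tyrobp and -0.04 for Laptm5. Tyrobp lay under the filter level on every array. Lyz2 was higher on both GIC arrays (6.78 and 6.96) than on both non-GIC arrays (6.63 and 6.33). Cd14 rose by 1.30, past the threshold over all genes, and Cd68 had 0.53. Markers near or under the filter level can understate a rise, so these medians argue only weakly against leukocytes as the main source. Without GIC replicate 1 the list's median was 0.787, with an adjusted p of 4.83e-08 by camera at the preset correlation; at an estimated one (0.947) and by fry (0.326) the list was not called even with all arrays. The deviations per array had been seen before and 1 GIC array is left in that fit, so how far the rise rests on GIC replicate 1 stays open. That array also had the highest 3' minus 5' signal of the pyruvate carboxylase control (0.72 against 0.42 to 0.51) and the highest mean deviation of the mural and fibroblast list (0.92). The actin, Gapdh and transferrin receptor controls showed no rise of that size on it (0.12, -0.31 and 0.94). RNA quality and culture conditions that differed between the sublines stay open.

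The lower cell cycle list could come from 1 GIC array. Without GIC replicate 1 its median was -0.187 and the camera call was lost (adjusted p = 0.146). The deviations per array had been seen before and fix this outcome, so it adds no evidence. The pyruvate carboxylase control had a 3' minus 5' signal of 0.72 on that array against 0.42 to 0.51 on the others. The Gapdh control went the other way, with -0.31 against -0.29 to -0.18. The actin control (0.12 against 0.09 to 0.11) and the transferrin receptor control (0.94 against 0.84 to 0.97) hardly set that array apart. Whether RNA handling or the growth of that culture caused the shift stays open.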
